A study of Mus musculus with 4 samples.

How the data were processed

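Single-cell RNA sequencing was carried out on the middle part of the colon of 7-week-old mice kept free of specified pathogens. Control mice drank clean water and treated mice drank 3% dextran sulfate sodium (DSS) for 2 days. The series holds 2 control and 2 DSS libraries, named here control 1, control 2, DSS 1 and DSS 2. The labels give a number to each library and do not state that libraries of 1 group came from separate animals. The p-values for genes and shares thus measure the spread between these libraries, which may be technical. The kit is a droplet kit that reads the 3-prime end of transcripts. Its labels name version 3 reagents for capture and version 2 reagents for library construction, and this difference was not resolved here. The labels give a target of 5000 cells per library, and the files hold 10966, 13014, 12778 and 13093 barcodes for control 1, control 2, DSS 1 and DSS 2.

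The deposited values are whole-number counts of unique molecular identifiers (UMIs) per gene and barcode, as the files hold them in 12 files, 3 per library. Cell Ranger 6.1.1 and the mouse genome build GRCm38 are named per the submitters' processing notes, and further settings of that step are not given in the sources used here. The files list 55450 genes, and all 55450 identifiers and symbols matched the GENCODE M21 annotation of GRCm38, from which positions were taken. Of the symbols, 108 belonged to more than 1 identifier.

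Cells were kept with at least 500 UMIs, at least 250 genes and at most 25% mitochondrial UMIs. Of 49851 barcodes, 44356 passed. The limit on mitochondrial UMIs removed 14.0% of barcodes in control 1, 17.4% in control 2, 5.16% in DSS 1 and 6.42% in DSS 2. Doublets were predicted per library with Scrublet in scanpy 1.11.5, with an expected rate of 0.8% per 1000 cells, and were removed after clustering. They made up 3.22%, 4.69%, 4.28% and 5.60% of the cells of control 1, control 2, DSS 1 and DSS 2. The 42351 kept cells comprised 9021, 10244, 11522 and 11564 cells, with median depths of 6087, 6297, 5790 and 4729 UMIs.

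Counts were scaled per cell and log-transformed, and 2000 variable genes and 40 principal components entered a graph of 20 neighbours that was clustered with leidenalg 0.10.2 at resolution 1, without integration of libraries. Each of the 39 clusters was named from marker genes that were fixed before the data were examined, as were the filters, tests, gene lists, alternatives and the rule for named genes, except where stated. A marker counted when it was detected in at least 15% of a cluster's cells at a level at least 2-fold that of the other cells, and a name needed at least 3 markers. Class names stand for cells that are like the named type by these markers. Clusters of the same name were pooled, which gave 18 of the 23 classes searched for. Neutrophil-like, mast-like, eosinophil-like, mesothelial-like and erythroid-like clusters were not found at resolution 1. A total of 5 clusters with 1157 kept cells stayed unnamed. Clusters 24, 34 and 36 consisted by more than 50% of predicted doublets. Clusters 20 and 27 carried pericyte markers without Notch3 and were led by genes of another kind (Rprm, Kit and Ano1 in cluster 20, Pcp4 and Cckar in cluster 27), and they were kept out of the pericytes by a rule set after the clusters had been seen. Cluster 20 made up 2.44%, 0.107%, 2.88% and 0.502% of the kept cells of control 1, control 2, DSS 1 and DSS 2, and cluster 27 made up 1.08%, 0.098%, 0.877% and 1.38%.

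UMI counts were summed per library and class, and the 12 classes with at least 30 cells in each library were tested, since cells are not replicates. Genes were tested with the two-sided quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, group as the sole term), with Benjamini-Hochberg adjustment within a class and a threshold of 0.05. Levels are given as CPM, the summed UMIs of a class scaled to a fixed total per library, as mean ± SD of n = 2 libraries. Fold changes are log2 of DSS over control, with the standard error (SE) of the fit. A counting interval is the exact binomial interval for UMIs pooled over the libraries of a group. It leaves out the spread between libraries and between cells. DESeq2 1.42.0 was run beside edgeR. Shares of cells were tested with the same edgeR test on cell numbers, with all kept cells of a library as the offset. With 2 libraries against 2, an exact two-sided permutation test cannot give a p below 0.333, so none was used. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over all 180 pairs of list and class. It asks whether a list's genes moved more than the other genes of the class. At this setting genes count as nearly independent, so its p-values compare genes with genes and do not measure the spread between libraries. The same test with an estimated correlation and the self-contained test fry were run beside it. A list entered a class when at least 5 members passed the filter. Of 27 lists meant for testing, 26 had a class to be tested in, and a list of sex-linked genes served to check the animals, with a like pattern in all 4 libraries. Differences between the responses of the 3 large epithelial classes were tested as interaction terms. Shares of the epithelial, immune and stromal compartments were added after the data had been seen.

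Genes named for the size of their change had an adjusted p under 0.05, a mean of at least 20 CPM in the higher group, both DSS libraries on the same side of both control libraries and a CPM in the class of at least 0.5 times that over all kept cells. Sex-linked genes, markers of the class and unnamed gene models were left out. The 10 largest rises and falls were taken in colonocytes, progenitors and goblet cells and 5 each way elsewhere, together with up to 4 members of each described list with the smallest p and a fixed panel, to which none of these limits applied. Where no gene passed, the 3 genes with the smallest p are given as values. A few genes that these rules name are not reported here. The ratio of the CPM in a class to that over all kept cells, called the class-to-all ratio, was taken in the group with the higher mean CPM. It is printed where it is low, since RNA free in the suspension enters every droplet.

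The tests were first run on simulated data drawn from the real means and library sizes with 200 changed genes per class. In progenitors 11 of 67 genes changed 2-fold, 51 of 67 changed 4-fold and 58 of 66 changed 8-fold were recovered, with 19 false among 146 calls. In colonocytes 5 of 67, 32 of 67 and 56 of 66 were recovered, with 11 false among 105 calls, and in goblet cells 2 of 67, 49 of 67 and 60 of 66, with 14 false among 129 calls. A simulated list changed 2-fold was called in 12 of 12 classes at the preset correlation and in 0 of 12 with an estimated correlation, and 0 of 600 unchanged lists were called. The simulated genes were drawn independently of each other, from a single mean per gene over all libraries. Cluster mixes that shift many genes of a library together were thus not simulated. The gene counts do not show how many changes of these sizes would pass in the real libraries. The list counts thus do not show how often the preset correlation calls unchanged lists whose members move together. The share test recovered 33 of 200 classes whose share was changed 8-fold (16.5%), with 4 calls among 1600 unchanged classes.

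Alternatives tried were other size factors, no filter on low counts, a term for the replicate number, leaving out each library in turn, at most 10% mitochondrial UMIs, at least 1000 UMIs per cell, keeping predicted doublets, Leiden resolutions 0.5 and 2, a filter on the class-to-all ratio, TMM scaling of cell numbers and shares within a compartment. Equal cell numbers per library, the larger progenitor cluster alone and the cells of a class in a single resolution 2 cluster, where it held at least 30 in each library, were added after the data had been seen. Where 1 library of a group is left out, the remaining one is taken to vary like the other group. No pair of libraries agreed within sampling noise. The chi-square per degree of freedom over genes was 809 for the control pair and 1177 for the DSS pair. Across groups it was 333 for control 2 and DSS 2 and 719.5 for control 1 and DSS 2, lower than for either pair within a group. It was 1232 for control 2 and DSS 1 and 1393 for control 1 and DSS 1. Pairs shared 28 to 41 barcodes.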

Results

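The data describe single cells of the mouse mid-colon after 2 days of 3% DSS in the drinking water, against clean water. DSS is a sulfated polysaccharide that injures the colonic lining and is widely used to cause colitis in mice. The comparison addresses the first stage of colitis, and each group held 2 libraries. The files held 101051573 and 101834659 UMIs for control 1 and control 2 and 108941875 and 109472082 UMIs for DSS 1 and DSS 2. After filtering, 42351 cells remained, with 1915 to 2226 genes per cell in the median of a library.

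The first question was whether the cell classes differed in their share of the tissue. Absorptive colonocytes, the surface cells that take up salt and water, made up 33.1% ± 14.5 (SD, n = 2) of control cells and 14.7% ± 10.8 of DSS cells. Epithelial progenitors of the crypt made up 13.3% ± 10.2 and 3.01% ± 2.82, and mucus-secreting goblet cells 8.22% ± 5.99 and 2.98% ± 0.0475. T cells made up 2.83% ± 0.172 of control cells and 7.95% ± 0.945 of DSS cells. Monocytes or macrophages made up 1.89% ± 0.0593 and 5.64% ± 3.52, and fibroblasts 18.8% ± 0.593 and 29.3% ± 8.82. In these 6 of the 18 classes, and in no other, both DSS libraries lay on the same side of both controls. With 2 libraries against 2, this many classes can fall on one side by chance alone. In colonocytes the side rested on a small gap between control 1 and DSS 2. By compartment, epithelial cells made up 56.2% ± 2.39 of control cells and 21.9% ± 13.7 of DSS cells (adjusted p = 0.126). Immune cells made up 14.5% ± 6.47 and 35.7% ± 17.5 (adjusted p = 0.126), and stromal cells 27.0% ± 2.17 and 39.3% ± 5.03 (adjusted p = 0.179). The edgeR test passed 0 of 18 classes, with a smallest adjusted p of 0.741 and a smallest unadjusted p of 0.112, for progenitors. How well each cell type came through dissociation was not measured.

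**Figure D1:**
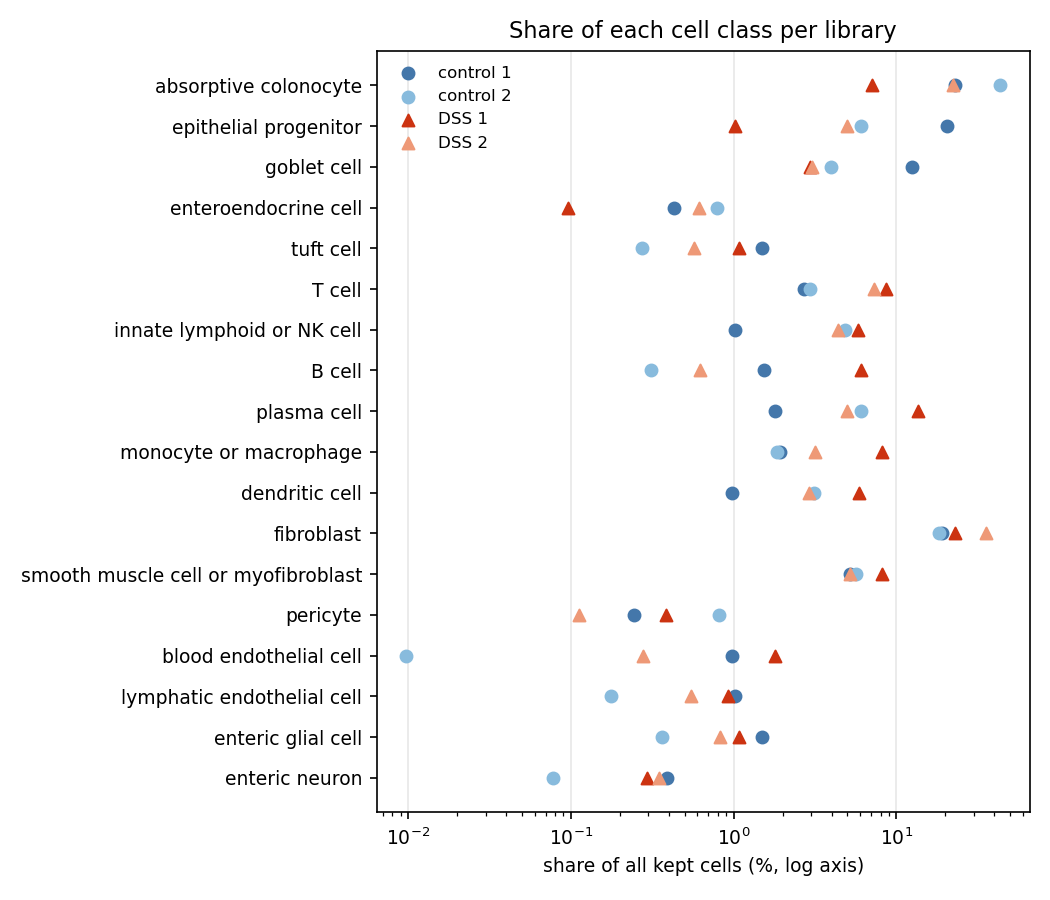
Share of each of the 18 cell classes among kept cells (percent, log axis), with 1 point per library for the 2 control and 2 DSS libraries. T cells were at 2.70% and 2.95% in control and 8.62% and 7.28% in DSS, and no class passed the test.

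In the edgeR test of all 4 libraries, single genes passed in epithelial progenitors and in none of the 11 other classes. Among genes that are not class markers and had a mean of at least 20 CPM in the higher group, the largest rise was that of Reg3b, a secreted lectin that acts against bacteria. It went from 8.19 CPM ± 6.59 in control to 1219 CPM ± 721 in DSS (SD, n = 2; log2 fold change 7.17, SE 0.72, adjusted p = 0.00257). Reg3g, a lectin of the same family, rose from 9.60 CPM ± 7.93 to 144 CPM ± 100 (4.08, SE 0.59, adjusted p = 0.00874). Ly6a, which encodes the surface protein Sca-1, rose from 51.5 CPM ± 11.3 to 459 CPM ± 243 (3.23, adjusted p = 0.00395). The chemokine genes Ccl20 (4.37, adjusted p = 0.0378) and Ccl9 (3.80, adjusted p = 0.0236) rose as well. So did Clu, which encodes the secreted chaperone clusterin (3.16, adjusted p = 0.0496), Apol10a (3.00), the immunity-related GTPase gene Igtp (2.77), AW112010 (2.65) and Gda, which encodes guanine deaminase (2.46). The largest fall among the same genes was that of Rgcc, a regulator of the cell cycle, from 165 CPM ± 87.6 to 3.37 CPM ± 1.18 (-5.69, SE 0.44, adjusted p = 0.000379). Hopx, a homeodomain-like cofactor, fell from 95.9 CPM ± 14.6 to 9.48 CPM ± 2.07 (-3.33, adjusted p = 0.000492). The water channel gene Aqp1 fell from 89.9 CPM ± 28.0 to 12.0 CPM ± 4.48 (-2.91, adjusted p = 0.00395). The matrix gene Prelp (-3.62), Tenm4 (-3.12), Bex1 (-2.95), the ephrin receptor gene Ephb3 (-2.71), Bex4 (-2.61) and Cnn3 (-2.55) fell too. Rnf43, which encodes a ligase that removes Wnt receptors, fell by 2.53 on the log2 scale. In all, 122 genes rose and 152 fell of 13584 tested (edgeR), of which 265 also passed with DESeq2. The class held 1852 and 619 cells in control 1 and control 2 and 117 and 578 in DSS 1 and DSS 2. The count of changed genes was 558 without control 1, 714 without control 2, 627 without DSS 1 and 247 without DSS 2. Ccl20 and Clu did not pass with DESeq2 (adjusted p = 0.0726 and 0.115) or without control 1 (0.0588 and 0.0654). Without DSS 1 Clu did not pass (1.38, adjusted p = 0.102), and the log2 fold changes of Ccl20 and Ccl9 were 2.31 and 2.27. Without DSS 2 Igtp did not pass (1.27, adjusted p = 0.444), and those of Apol10a and Tenm4 were 1.88 and -1.92. At resolution 2 the class was another mix of clusters in the 2 groups. There cluster 8, led by Clca3b and named epithelial progenitor, held 1152, 388, 16 and 38 of its cells in control 1, control 2, DSS 1 and DSS 2. Cluster 9, led by Sult1c2, held 439, 66, 85 and 437 and stayed unnamed at that resolution. Most DSS cells of the class (85 of 117 and 437 of 578) were thus not named progenitors there. Leading genes of cluster 9 included Aqp4, Hao2, Gsdmc2 and Gsdmc4, which also led the colonocyte cluster 7 of resolution 1. A further 148, 13, 186 and 58 cells of cluster 9 belonged to the colonocyte class. In the progenitors of cluster 9 alone, edgeR passed 0 of 11373 genes, with 467 at an unadjusted p under 0.05. Of 40 named genes tested there 39 had the same direction as in the class, with Ephb3 (0.90) as the exception, and 24 had over 50% of their log2 fold change. Reg3b, Ly6a and Hopx lay at 5.37, 2.39 and -2.02 (adjusted p = 0.172 each), Clu at 3.36 and Igtp at 2.87 (0.763 and 0.384), and Rgcc and Prelp at -1.40 and -0.17 (0.976 and 1). Values there that were over 1.5 times smaller than in the class were also those of Ccl20 (2.73), Reg3g (2.04), Apol10a (1.79), Gda (1.15), Aqp1 (-1.44), Tenm4 (-1.36), Rnf43 (-1.36), Cnn3 (-0.90), Bex4 (-0.87) and Bex1 (-0.79).

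On GRCm38, Reg3b (ENSMUSG00000071356) lies on chromosome 6 from 78370657 to 78373466 and Reg3g (ENSMUSG00000030017) on chromosome 6 from 78466269 to 78468872. Ly6a (ENSMUSG00000075602) lies on chromosome 15 from 74994877 to 74998031. Ccl20 (ENSMUSG00000026166) lies on chromosome 1 from 83116766 to 83119167 and Clu (ENSMUSG00000022037) on chromosome 14 from 65968483 to 65981547. Rgcc (ENSMUSG00000022018) lies on chromosome 14 from 79288756 to 79301645. Hopx (ENSMUSG00000059325) lies on chromosome 5 from 77086988 to 77115121 and Aqp1 (ENSMUSG00000004655) on chromosome 6 from 55336432 to 55348555. Igtp (chromosome 11, 58199556 to 58207591) overlaps Irgm2 (chromosome 11, 58199618 to 58222782) in the annotation. Reg3b and Reg3g, Bex1 and Bex4, and the Apol10 genes have close relatives. The division of reads among all of these is uncertain.

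**Figure D2:**
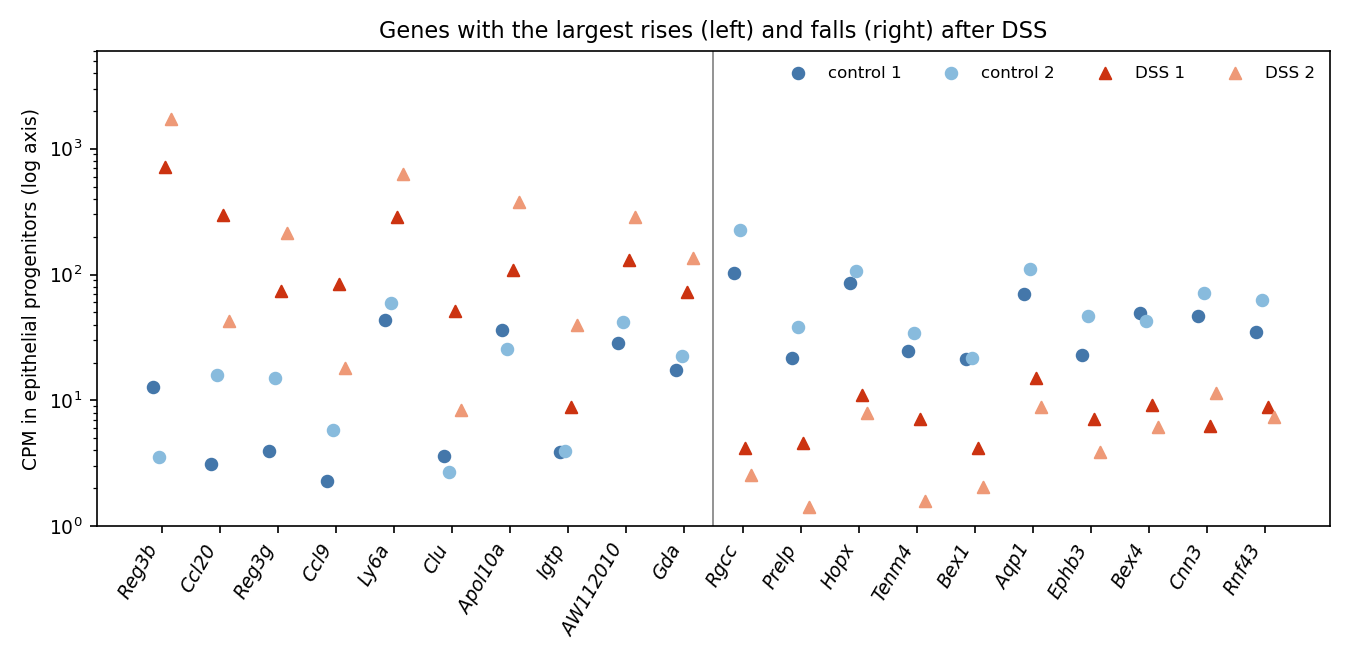
Level of the 10 largest rises and 10 largest falls in epithelial progenitors (CPM, log axis), with 1 point per library for 2 control and 2 DSS libraries. The genes shown are not class markers and had a mean of at least 20 CPM in the higher group. They also had a class-to-all ratio of at least 0.5 and both DSS libraries on the same side of both controls. Reg3b lay at a mean of 8.19 CPM in control and 1219 CPM in DSS, and Rgcc at 165 CPM and 3.37 CPM.

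Stem cell and Wnt target genes, which mark the crypt base, were lower in progenitors after DSS as a group. The median log2 fold change was -2.01 with 15 of 16 members lower (camera adjusted p = 1.91e-38, and adjusted p = 0.59 with an estimated correlation). Of these, 10 fell in the test over all genes, and 15 fell and 1 rose adjusted over the list alone. Lgr5, the receptor that marks crypt-base stem cells, had 1392 UMIs in control cells and 0 in DSS cells. This is at least 165-fold lower against a floor of 3 UMIs over the DSS group (adjusted p = 0.000492), and the list's median was also -2.01 with Lgr5 at that bound. Ascl2, a transcription factor of these stem cells, had 1950 and 1 UMIs (ratio of levels 0.00144, 95% counting interval 3.65e-05 to 0.00804, adjusted p = 0.000151). Axin2, a feedback inhibitor of Wnt signalling, had 2469 and 6 UMIs (-7.27, adjusted p = 0.000151), and Cdca7 fell by 2.35 on the log2 scale (adjusted p = 0.00412). These 4 genes are among the 8 members that also served as markers of the class, and the median of the 8 others was -1.40. Over all epithelial cells together, Lgr5 had 949, 719, 3 and 5 UMIs in control 1, control 2, DSS 1 and DSS 2. Ascl2 had 1324, 1027, 6 and 7 UMIs there and Axin2 2111, 1500, 24 and 20. Proliferation genes were also lower in progenitors as a group, in 31 of 32 members (median -0.62, camera adjusted p = 2.56e-08, and adjusted p = 0.59 with an estimated correlation). Of these, 1 fell over all genes and 7 adjusted over the list alone. The 1 was the replication helicase gene Mcm6 (-1.35, adjusted p = 0.0402, and 0.342 without DSS 2). Cluster 3 held most progenitors in all 4 libraries, and the cycling cluster 22 held the rest. Cluster 3 was itself mostly made of the resolution 2 clusters 8 and 9, whose shares differed between the groups. In progenitors of the resolution 2 cluster 9 alone, the median of the stem cell list was -0.27 with 8 of 14 members lower, and Axin2 had 97, 20, 1 and 4 UMIs in control 1, control 2, DSS 1 and DSS 2 (-4.81, adjusted p = 0.112), while Cdca7 lay at -1.30 (0.594). The median of the proliferation list was -0.68 there. Cluster 8 had too few cells in DSS 1 to be tested. Lgr5 (ENSMUSG00000020140) lies on chromosome 10 from 115450311 to 115587780. Ascl2 (ENSMUSG00000009248) lies on chromosome 7 from 142966829 to 142969264 and Axin2 (ENSMUSG00000000142) on chromosome 11 from 108920349 to 108950783.

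Regenerative and fetal-like genes, which mark epithelium under repair, were higher in progenitors as a group. The median was 0.87 with 16 of 20 members higher (camera adjusted p = 1.86e-10, and adjusted p = 0.59 with an estimated correlation), and 0.47 in the resolution 2 cluster 9 alone. Over all genes 5 rose, and 9 rose adjusted over the list alone. Besides Ly6a and Clu, the annexin genes Anxa3 (1.98, adjusted p = 0.00412) and Anxa8 (1.78, adjusted p = 0.0191, class-to-all ratio 0.473) rose. In the resolution 2 cluster 9 alone they lay at 0.96 and 0.47 (adjusted p = 0.486 and 1). Msln, which encodes mesothelin, had 0 UMIs in control and 46 in DSS, at least 43.1-fold higher against a floor of 3 UMIs over the control group (adjusted p = 0.00781). The list's median was 0.57 without DSS 2 and 0.58 without control 1. All 33 interferon-gamma and antigen presentation genes were higher (median 1.45, camera adjusted p = 1.05e-19, and adjusted p = 0.59 with an estimated correlation). Of them 8 rose over all genes and 20 adjusted over the list alone, and the median was 0.83 without DSS 2. Examples were Irgm2 (2.49, adjusted p = 0.0131), the immunoproteasome subunit gene Psmb8 (1.67, 0.0153) and the peptide transporter gene Tap1 (2.04, 0.0277). Without DSS 2 none of these 3 passed (adjusted p = 0.117 for Irgm2, whose log2 fold change was then 1.64, with 0.0614 for Psmb8 and 0.152 for Tap1). All 28 type I interferon response genes were higher too (median 1.35, camera adjusted p = 2.71e-22, and adjusted p = 0.59 with an estimated correlation). Of them 7 rose over all genes and 21 adjusted over the list alone. They included the nucleic acid sensor gene Zbp1 (3.62, adjusted p = 0.00727, class-to-all ratio 0.483), Isg15, a ubiquitin-like modifier (3.12, 0.0108, class-to-all ratio 0.43), Ifi44 (3.26, 0.0222) and Parp14 (1.40, 0.0236). Ifi44 did not pass without control 1 (2.97, adjusted p = 0.0576), nor Parp14 without DSS 2 (0.0803). NF-kB and inflammatory cytokine genes were higher in 30 of 31 members (median 0.77, camera adjusted p = 3.49e-09, and adjusted p = 0.59 with an estimated correlation). Over all genes 2 rose, Ccl20 and Ccl5, and 5 rose adjusted over the list alone, and the median was 1.37 without control 2. Ccl5 (2.48, adjusted p = 0.0236, and 0.198 without DSS 2) had a class-to-all ratio of 0.0639. Markers of immune cells, which progenitors should lack, had a median log2 fold change of 0.95 in progenitors.

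Genes of colonocyte ion and nutrient transport were higher in progenitors as a group, in 18 of 22 members (median 0.69, camera adjusted p = 7.35e-05, and adjusted p = 0.59 with an estimated correlation). Over all genes 2 rose and 1 fell, against 11 and 1 adjusted over the list alone. The lactate and butyrate carrier gene Slc16a1 (1.15, adjusted p = 0.0376) and the bile acid carrier gene Slc51b (1.57, 0.0499, class-to-all ratio 0.362) rose, and Aqp1 fell. In the resolution 2 cluster 9 alone Slc16a1 and Slc51b lay at 0.46 and 0.74 (adjusted p = 1 for both). The call of the list ended without control 1 (0.48, adjusted p = 0.0802), and the median was 0.44 without DSS 2 and 0.20 in the resolution 2 cluster 9 alone. Slc16a1 did not pass without DSS 1 or DSS 2 (adjusted p = 0.0519 and 0.206). Slc51b did not pass without control 1 or DSS 2 (1.36 and 0.88, adjusted p = 0.0739 and 0.525). All 21 cholesterol synthesis genes were higher (median 0.75, camera adjusted p = 1.51e-09, and adjusted p = 0.59 with an estimated correlation). Of them 0 passed over all genes and 13 adjusted over the list alone, and the median was 0.37 in the resolution 2 cluster 9. Junction genes were higher as a group in 22 of 25 members (median 0.37, camera adjusted p = 0.0205, and adjusted p = 0.722 with an estimated correlation). This call was lost without DSS 2 (0.18, adjusted p = 0.506) and without control 1 (0.28, 0.0676), and the median was 0.16 in the resolution 2 cluster 9. Its member Cldn2, a pore-forming claudin, fell from 148 CPM ± 18.5 to 41.3 CPM ± 3.01 (-1.76, adjusted p = 0.00622), and lay at -0.60 in that cluster (adjusted p = 1). Cldn2 (ENSMUSG00000047230, chromosome X, 139800828 to 139811386) is also 1 of the 10 leading genes of cluster 3. Of the fixed panel, Retnlb, an antibacterial goblet cell product, fell by 1.40 on the log2 scale (adjusted p = 0.0277, and 0.274 without DSS 2) with a class-to-all ratio of 0.0564. Muc2 (-0.81, adjusted p = 0.148), Saa1 (0.91, 0.28) and Duox2 (-0.28, 0.775), with class-to-all ratios of 0.052, 0.125 and 0.237, did not pass, and Lcn2 and Nos2 were too low to be tested.

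In goblet cells the same families moved as groups although no single gene passed. Stem cell and Wnt target genes were lower in 15 of 17 members (median -1.30, camera adjusted p = 4.16e-25, and adjusted p = 0.59 with an estimated correlation). Adjusted over the list alone 13 fell and 1 rose, and the median without the members that are progenitor markers was -1.04. Interferon-gamma and antigen presentation genes were higher in 31 of 31 members (median 1.53, camera adjusted p = 3.47e-27, and adjusted p = 0.55 with an estimated correlation), 23 of them passing adjusted over the list alone. Markers of immune cells had a median log2 fold change of 2.07 in goblet cells. Type I interferon response genes were higher in 27 of 29 members (median 1.51, camera adjusted p = 2.71e-27, and adjusted p = 0.55 with an estimated correlation). Adjusted over the list alone 24 rose and 1 fell. All 32 proliferation genes were lower (median -0.80, camera adjusted p = 1.64e-13, and adjusted p = 0.59 with an estimated correlation). Regenerative and fetal-like genes were higher in 17 of 20 members (median 0.94, camera adjusted p = 0.0001, and adjusted p = 0.59 with an estimated correlation). Their median was 0.37 without DSS 2 and 0.44 without control 1. Transport genes were higher in 22 of 26 members (median 0.74, camera adjusted p = 0.000132, and adjusted p = 0.608 with an estimated correlation). Their median was 0.44 without DSS 2 and 1.34 without control 2. The genes with the smallest p were Hopx (63.8 CPM ± 2.26 in control and 8.23 CPM ± 1.75 in DSS), Wfdc18 (204 CPM ± 27.3 and 28.6 CPM ± 4.70) and Axin2 (24.7 CPM ± 10.3 and 1.11 CPM ± 0.245). Each had an adjusted p of 0.0747, as did the guanylate-binding protein gene Gbp2 (log2 fold change 3.89, class-to-all ratio 0.347). Lgr5 had 211 and 3 UMIs (ratio 0.0257, 95% counting interval 0.00526 to 0.0762, adjusted p = 0.098). The main mucin gene Muc2 lay at 24832 CPM ± 407 and 17965 CPM ± 1124 (-0.29, adjusted p = 0.894). Reg3b lay at 4.99 on the log2 scale (adjusted p = 0.375), Reg3g at 2.94 (0.367), Saa1 at 1.88 (0.219, class-to-all ratio 0.431) and Retnlb at -0.07 (0.981). Duox2 lay at -0.11 (adjusted p = 0.94), and Lcn2 and Nos2 were too low to be tested. The edgeR test passed 0 of 13136 genes, with 1774 at an unadjusted p under 0.05, and DESeq2 passed 425. The edgeR count ranged from 0 to 113 when 1 library was left out. At resolution 2, cluster 12, led by Spink4, Spdef and Agr2, held 649, 330, 35 and 213 goblet cells of control 1, control 2, DSS 1 and DSS 2, and cluster 18, led by Zg16, Clca1 and Tff3, held 455, 39, 298 and 133. In clusters 12 and 18 alone, edgeR passed 7 and 0 genes, with 1105 and 1251 at an unadjusted p under 0.05. The medians there were -1.23 and -0.80 for the stem cell list, 1.84 and 1.24 for the interferon-gamma list, 0.93 and 1.29 for the type I interferon list and 0.88 and 1.17 for the regenerative list. That of the proliferation list was 0.16 in cluster 12 and -0.33 in cluster 18.

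In absorptive colonocytes, interferon-gamma and antigen presentation genes were higher as a group in 27 of 33 members (median 0.97, camera adjusted p = 2.04e-09, and adjusted p = 0.59 with an estimated correlation). Adjusted over the list alone 7 rose, and the median was 0.60 without control 1. Endoplasmic reticulum stress genes, which help newly made proteins to fold, were higher in 19 of 25 members (median 0.65, camera adjusted p = 2.96e-07, and adjusted p = 0.59 with an estimated correlation), 5 of them passing adjusted over the list alone. Regenerative and fetal-like genes were higher in 16 of 19 members (median 0.61, camera adjusted p = 0.00096, and adjusted p = 0.684 with an estimated correlation). That call was lost without DSS 2 (-0.01, adjusted p = 0.613) and without control 1 (0.46, 0.207), and the median was 1.08 without control 2 and 0.96 without DSS 1. All 13 mitochondrially encoded genes were lower (median -0.53, camera adjusted p = 0.000288, and adjusted p = 0.59 with an estimated correlation). The median share of mitochondrial UMIs in colonocytes was 12.96%, 12.8%, 7.84% and 4.55% in control 1, control 2, DSS 1 and DSS 2. Transport genes were lower in 17 of 24 members, of which 4 members are class markers (median -0.45, camera adjusted p = 0.00257, and adjusted p = 0.667 with an estimated correlation). This call was lost without control 2 (-0.21, adjusted p = 0.23) and without DSS 1 (-0.43, 0.0888), and the median was -0.77 without DSS 2. The water channel gene Aqp8, itself a class marker, lay at 1150 CPM ± 342 in control and 399 CPM ± 102 in DSS (-1.64, adjusted p = 0.317). The genes with the smallest p were Pdzd7 (-3.75), Spink4 (-2.97, class-to-all ratio 0.0522) and Mier3 (-2.28, 130 CPM ± 2.06 and 28.9 CPM ± 0.446), each with an adjusted p of 0.139. Reg3b lay at 22.6 CPM ± 31.6 and 428 CPM ± 296 (4.08, adjusted p = 0.466). Reg3g lay at 3.08 (adjusted p = 0.449), Saa1 at -0.21 (0.9), Nos2 at -0.26 (0.919) and Duox2 at -0.90 (0.495). Retnlb lay at -1.83 (adjusted p = 0.342, class-to-all ratio 0.0417) and Muc2 at -1.72 (0.255, class-to-all ratio 0.0494). Lgr5 had 26 and 0 UMIs, at least 7.42-fold lower (adjusted p = 0.277, class-to-all ratio 0.0413), and Lcn2 was not tested. With edgeR 0 of 14548 genes passed, with 1550 at an unadjusted p under 0.05, and DESeq2 passed 268. Leaving out 1 library at a time, the edgeR count ranged from 10 to 562. Different clusters held most colonocytes in the libraries. Cluster 0, led by Aqp8, held 1164, 3632, 242 and 678 cells of control 1, control 2, DSS 1 and DSS 2. Cluster 7, led by Aqp4, held 890, 505, 484 and 151, and cluster 37, led by Ifit1, Ifit2 and Isg15, held 5, 23, 8 and 69. Cluster 6, led by Ly6g, Il1rn, Reg3b and Areg, held 9, 283, 79 and 1688. Within the resolution 2 clusters 0, 5 and 7 alone, edgeR passed 63, 92 and 162 genes. The medians there were -0.08, -0.18 and -0.34 for transport genes, 0.26, 0.23 and 0.44 for regenerative genes and -0.44, 0.02 and -0.34 for mitochondrially encoded genes. The median depth of colonocytes was 6848, 8428, 20584 and 14802 UMIs.

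The interferon-gamma and antigen presentation list was called higher in all 12 classes at the preset correlation. Outside the epithelium its median log2 fold change was 1.01 in fibroblasts (31 of 32 members higher, camera adjusted p = 8.07e-21) and 0.99 in smooth muscle cells or myofibroblasts (26 of 27, 8.18e-22). It was 0.91 in enteric glia (19 of 23, 4.89e-05), 0.56 in monocytes or macrophages (24 of 31, 5.52e-08) and 0.47 in innate lymphoid or NK cells (25 of 28, 6.73e-08). In dendritic cells it was 0.33 (25 of 31, 6.12e-08), in B cells 0.33 (20 of 20, 0.00214), in plasma cells 0.28 (24 of 28, 0.000646) and in T cells 0.21 (25 of 29, 0.00306). Each of these 9 calls had an adjusted p of 0.59 with an estimated correlation. Markers of immune cells had a median log2 fold change of 0.90 in fibroblasts, 0.60 in smooth muscle cells, 0.04 in glia and 0.45 in colonocytes, classes that should lack them. Within single clusters the median was 0.08 and -0.08 in plasma cell clusters 5 and 19 and 0.07 and 0.22 in T cell clusters 13 and 16. In clusters 14 and 17 of innate lymphoid or NK cells it was 0.37 and 0.16. An example in macrophages was Gbp2 (38.3 CPM ± 6.13 and 293 CPM ± 202, log2 fold change 2.89, adjusted p = 1). In enteric glia the chemokine gene Cxcl10, a member of the list, had a log2 fold change of -3.62 (adjusted p = 0.633). The call ended in glia without control 1 (0.56, adjusted p = 0.214) and in T cells without DSS 1 (0.08, 0.478) and without control 2 (0.35, 0.0691). Without DSS 2 the median was 0.48 in fibroblasts, 0.27 in glia, 0.35 in macrophages and 0.66 in B cells. Without DSS 1 it was 0.19 in innate lymphoid or NK cells, 0.21 in B cells and 0.11 in plasma cells. Without control 1 it was 0.60 in fibroblasts, 0.61 in smooth muscle cells, 0.37 in macrophages and 0.80 in B cells. Without control 2 it was 1.61 in fibroblasts, 1.75 in smooth muscle cells, 0.70 in innate lymphoid or NK cells and 0.45 in plasma cells.

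**Figure D3:**
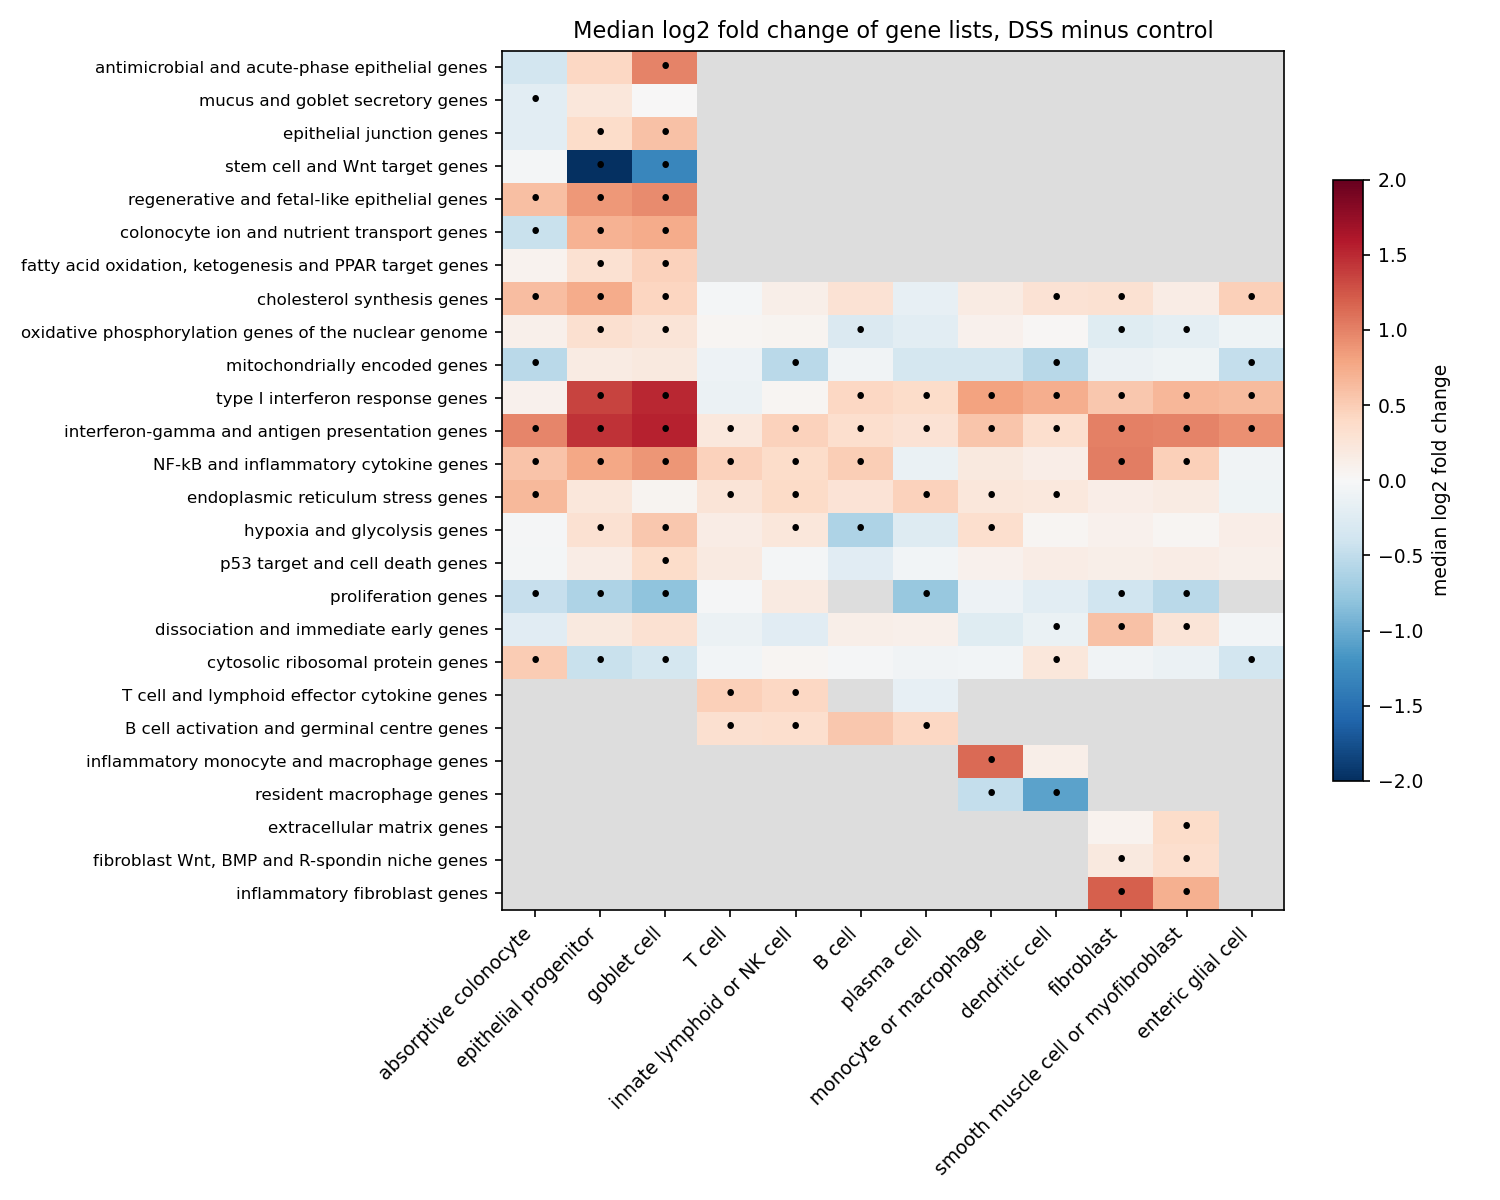
Median log2 fold change (DSS over control) of the members of 26 gene lists (vertical) in 12 cell classes (horizontal), with a dot where the list passed at the preset correlation and grey where it was not tested. The interferon-gamma list has a dot in all 12 classes, and the median of the stem cell and Wnt target list was -2.01 in progenitors.

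In monocytes or macrophages, inflammatory monocyte and macrophage genes were higher as a group in 19 of 24 members, with 2 class markers in the list (median 1.14, camera adjusted p = 3.51e-15, and adjusted p = 0.59 with an estimated correlation). Of them 3 rose adjusted over the list alone. The median was 0.27 without DSS 2, 1.78 without DSS 1 and 2.26 without control 2. At resolution 2 most macrophages of control 1 lay in cluster 24, led by Pf4, Ccl12 and Mrc1. Most of those of control 2, DSS 1 and DSS 2 lay in cluster 17, led by Lyz2, Clec7a and Mmp13. Cluster 17 had too few cells in control 1 to be tested. The values over the class do not separate this mix from a change within cells. The genes with the smallest p in the class were Chil3, a chitinase-like protein of recruited monocytes (3.51 CPM ± 1.54 and 115 CPM ± 71.6), the coagulation factor gene F10 (log2 fold change 4.06) and Ly6i. Ly6i had 3 and 239 UMIs (ratio 15.8, 95% counting interval 5.36 to 77.4), and all 3 genes had an adjusted p of 0.704. Plac8 lay at 170 CPM ± 107 and 1011 CPM ± 538 (2.54, adjusted p = 1). The cytokine gene Il1b lay at 2052 CPM ± 924 and 2553 CPM ± 650 (0.29). Tnf lay at 0.73, S100a8 at 2.89, Cxcl2 at -0.44 and Ccl2 at -0.13 on the log2 scale, and like Il1b each had an adjusted p of 1. Nos2 was not tested. Cells of a neutrophil-like resolution 2 cluster, led by S100a9 and S100a8, were part of the class. These were 0, 1, 7 and 11 cells in control 1, control 2, DSS 1 and DSS 2. Type I interferon response genes were higher in 28 of 30 members (median 0.80, camera adjusted p = 9.47e-20, and adjusted p = 0.59 with an estimated correlation). Of them 3 rose adjusted over the list alone, and the median was 1.28 without control 1. Resident macrophage genes, of which 5 of 20 are class markers, were lower in 17 members (median -0.47, camera adjusted p = 0.003, and adjusted p = 0.608 with an estimated correlation). This call was lost without control 1 (-0.29, adjusted p = 0.0632) and without DSS 2 (-0.31, 0.128), and the median was -0.78 without DSS 1 and -0.04 in the resolution 2 cluster 24 alone. In macrophages 0 of 9004 genes passed with edgeR, with 308 at an unadjusted p under 0.05, and DESeq2 passed 13. Without 1 library the edgeR count ranged from 0 to 63.

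In dendritic cells, resident macrophage genes were lower as a group in 19 of 19 members (median -1.07, camera adjusted p = 1.6e-15, and adjusted p = 0.59 with an estimated correlation). Adjusted over the list alone 5 fell, and values included those of the lipid carrier gene Apoe (-2.21), Pf4 (-2.06) and the complement gene C1qa (-1.45), each with an adjusted p of 1 over all genes. The median depth of dendritic cells was 2495, 1311.5, 6795 and 4980 UMIs in control 1, control 2, DSS 1 and DSS 2, with 1.91%, 7.25%, 2.56% and 1.6% mitochondrial UMIs. Cluster 38, led by Ccl22, Fscn1 and Apol7c, held 0, 2, 41 and 16 dendritic cells. At resolution 2 the other dendritic cells lay mostly in cluster 21, which is led by Retnla and Ccl9 and was named monocyte or macrophage (49, 237, 261 and 148 cells), and in cluster 27, led by Cd209a and Ccl17 (34, 73, 362 and 169). The median of the resident macrophage list was -0.61 in cluster 21 with 16 of 18 members lower, and -0.15 in cluster 27 with 9 of 12. Genes with among the smallest p in the class were the chemokine gene Ccl17 (122 CPM ± 39.8 and 697 CPM ± 305, 2.62) and Spink4 (-4.04), each with an adjusted p of 1. In this class 0 of 9596 genes passed with edgeR, with 224 at an unadjusted p under 0.05, and DESeq2 passed 4. Without 1 library the edgeR count ranged from 0 to 8.

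In T cells, effector cytokine genes were higher as a group in 16 of 21 members (median 0.48, camera adjusted p = 3.65e-05, and adjusted p = 0.59 with an estimated correlation). Their median was 0.30 without DSS 2 and 1.09 without control 2. Members with the smallest p included the inhibitory cytokine gene Il10 (28.7 CPM ± 15.3 and 75.2 CPM ± 27.1), the costimulatory receptor gene Icos (235 CPM ± 142 and 526 CPM ± 265) and Il17a (6.39 CPM ± 6.93 and 19.2 CPM ± 10.0). Each of these had an adjusted p of 1. Cluster 16, led by Icos, Tnfrsf4 and Ctla4, held 44 of 244, 103 of 302, 414 of 993 and 338 of 842 T cells in control 1, control 2, DSS 1 and DSS 2. The median of the effector list was 0.35 and 0.11 in the resolution 2 clusters 15 and 19. In innate lymphoid or NK cells, NF-kB and inflammatory cytokine genes were higher in 22 of 27 members (median 0.36, camera adjusted p = 9.61e-05, and adjusted p = 0.59 with an estimated correlation). The median there was 0.20 without DSS 2 and 0.88 without control 2, and 0.16 and 0.30 in the resolution 2 clusters 25 and 31. Control 2 stood apart in this class, with a median depth of 939.5 UMIs and 7.16% mitochondrial UMIs, against 2077 to 3436 UMIs and 2.5% to 4.03% in the other libraries. Cluster 17 held 310 of its 492 cells of that class. At resolution 2 part of the class lay in clusters named T cell, mainly cluster 33 (12, 251, 45 and 51 cells in control 1, control 2, DSS 1 and DSS 2) and cluster 46 (10, 22, 86 and 58), so that in control 2 the comparison rests in large part on cells named T cells there. In that class Spink4 (-4.01), the granzyme gene Gzmc (37.1 CPM ± 25.2 and 304 CPM ± 31.7) and the mast cell protease gene Mcpt2 had the smallest p (adjusted p = 0.654 each). Mcpt2 had 3 and 614 UMIs (ratio 48.9, 95% counting interval 16.7 to 238). The related genes Mcpt1 and Mcpt8, chosen after their values were seen, lay at 4.89 and 3.41 (adjusted p = 0.971 and 0.9999). Whether mast cells were part of the class was not tested. In B cells, of which control 2 held 32, hypoxia and glycolysis genes were lower in 14 of 17 members (median -0.62, camera adjusted p = 0.000448, and adjusted p = 0.59 with an estimated correlation). The median was -0.26 over the 15 members with a class-to-all ratio of at least 0.5. Colonocyte transcripts such as Krt20 (-2.18, adjusted p = 0.718) and Car4 (-2.29, 0.492), chosen after their values were seen, were lower in B cells too. The smallest p there were those of Spink4 (-3.14, adjusted p = 0.0808), Mep1a (-2.73, 0.242) and Sult1d1 (-2.47, 0.492). In T cells they were those of Spink4 (-3.42, adjusted p = 0.175), Clca3b (-3.39, 0.417) and Agr2 (-2.38, 0.417), all transcripts of epithelial cells (class-to-all ratios 0.122, 0.0973 and 0.0787). With edgeR 0 genes passed in T cells, innate lymphoid or NK cells and B cells. At an unadjusted p under 0.05 the counts were 202, 192 and 204, and with DESeq2 they were 5, 4 and 7. Leaving out 1 library at a time, the edgeR counts ranged from 3 to 88, from 3 to 8 and from 0 to 70.

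In plasma cells, endoplasmic reticulum stress genes were higher as a group in 25 of 26 members, with 2 class markers in the list (median 0.46, camera adjusted p = 7.06e-07, and adjusted p = 0.59 with an estimated correlation). Their median was 0.30 without DSS 1. Plasma cells had median depths of 8959, 3861.5, 14675 and 9493 UMIs in control 1, control 2, DSS 1 and DSS 2. Cluster 19, whose median depth was 1088 UMIs, held 56 of 162, 287 of 624, 153 of 1567 and 108 of 574 of them. Proliferation genes were lower in 28 of 31 members (median -0.76, camera adjusted p = 4.73e-09, and adjusted p = 0.59 with an estimated correlation), with a median of -0.03 in the resolution 2 cluster 1 alone. The antibody light chain segments Igkv4-74 (2 and 937 UMIs, ratio 93.4, 95% counting interval 25.8 to 772, adjusted p = 0.0854) and Igkv4-63 (0 and 289 UMIs, at least 19.2-fold higher, 0.3) had among the smallest p. Such segments have many close relatives, so their counts are uncertain. Whether a few cells held most of these UMIs was not tested. Spink4 (-3.15, adjusted p = 0.264) was the other gene with a small p, and the heavy chain gene Ighg2b lay at 112 CPM ± 55.2 and 1061 CPM ± 886 (adjusted p = 0.647). In this class 0 of 10591 genes passed with edgeR, with 482 at an unadjusted p under 0.05, and DESeq2 passed 29. Without 1 library the edgeR count ranged from 0 to 142.

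In fibroblasts, inflammatory fibroblast genes were higher as a group in 23 of 25 members (median 1.20, camera adjusted p = 9.67e-21, and adjusted p = 0.59 with an estimated correlation). Adjusted over the list alone 5 rose, and the median was 0.20 without DSS 2. All 30 NF-kB and inflammatory cytokine genes were higher (median 1.02, camera adjusted p = 5.19e-14, and adjusted p = 0.59 with an estimated correlation). Their median was 0.13 without DSS 2, 0.52 without control 1 and 2.14 without control 2. The acute-phase gene Saa3 had the smallest p (1.24 CPM ± 0.260 and 29.5 CPM ± 5.27, adjusted p = 0.148). Nrg1, a growth factor that acts on epithelial cells, followed (10.4 CPM ± 3.60 and 131 CPM ± 5.14, adjusted p = 0.188), and then Spink4 (-3.09, adjusted p = 0.313). The interleukin-33 receptor gene Il1rl1 (3.07), the matrix protease gene Mmp10 (2.94), Il6 (1.06), Cxcl1 (1.67), Ccl2 (2.23), Grem1 (0.43), Rspo3 (0.74) and Il33 (-0.00) each had an adjusted p of 1. Gli1, a transcription factor of hedgehog signalling, lay at 31.2 CPM ± 5.95 and 4.34 CPM ± 0.594 (-2.72, adjusted p = 0.313). The edgeR test passed 0 of 14995 genes, with 409 at an unadjusted p under 0.05. DESeq2 passed 38, Saa3 (adjusted p = 4.53e-15) and Nrg1 (6.71e-18) among them. Without 1 library the edgeR count ranged from 0 to 13. Cluster 1, led by Tnfaip6, Has1 and Ptx3, held 222 of 1733, 485 of 1882, 232 of 2658 and 2229 of 4110 fibroblasts in control 1, control 2, DSS 1 and DSS 2. Over 7 resolution 2 clusters the median ranged from -0.08 to 1.88 for inflammatory fibroblast genes and from 0.08 to 1.55 for NF-kB genes. Cluster 2 of that resolution, with 1, 197, 26 and 1856 cells in control 1, control 2, DSS 1 and DSS 2, was left out. Control 1 and DSS 1 held too few of its cells for a test. Leading genes of cluster 2 included the inflammatory fibroblast genes Has1, Cxcl1, Ccl2, Il6 and Ccl7. Immediate early genes, which also answer to dissociation, were higher as a group in fibroblasts too (median 0.58, camera adjusted p = 3.53e-09, and adjusted p = 0.597 with an estimated correlation). That call was lost without control 1 (-0.01, adjusted p = 0.663), and the median was 1.44 without control 2.

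In smooth muscle cells or myofibroblasts, inflammatory fibroblast genes were higher as a group in 13 of 14 members (median 0.71, camera adjusted p = 1.14e-06, and adjusted p = 0.59 with an estimated correlation). This call was lost without control 1 (0.31, adjusted p = 0.0782) and without DSS 2 (0.22, 0.218), and the median was 2.32 without control 2 and 1.39 without DSS 1. Extracellular matrix genes were higher in 28 of 32 members (median 0.37, camera adjusted p = 3.51e-07, and adjusted p = 0.59 with an estimated correlation), a call lost without control 1 (0.21, adjusted p = 0.0833). Their median was 0.61 without control 2, 0.56 without DSS 2 and 0.21 without DSS 1, and 0.02 and 0.27 in the resolution 2 clusters 11 and 29. The immediate early list was higher here too (median 0.26, camera adjusted p = 0.000688, and adjusted p = 0.722 with an estimated correlation). This call was lost without DSS 2 (0.01, adjusted p = 0.14) and without control 1 (-0.24, 0.101), and the median was 1.22 without control 2. Genes with among the smallest p were Reg4 (-4.47, class-to-all ratio 0.0848) and Aqp4 (-2.19, ratio 0.191), each with an adjusted p of 1. In enteric glia the smallest p were those of the receptor gene Ramp1 (248 CPM ± 21.5 and 32.3 CPM ± 11.5), Spink4 (-4.10) and Cpe (-3.18), each with an adjusted p of 0.361. With edgeR 0 of 11844 genes passed in smooth muscle cells and 0 of 4829 in glia. At an unadjusted p under 0.05 the counts were 221 and 107, and with DESeq2 they were 5 and 8. Without 1 library the edgeR counts ranged from 0 to 53 and from 3 to 26.

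Spink4, a secreted product of goblet cells, was lower in the DSS libraries in all 12 classes tested, with log2 fold changes from -4.10 in glia to -1.15 in goblet cells. It passed in progenitors (-1.71, adjusted p = 0.0236), with a class-to-all ratio of 0.0717. In classes that should lack it, its class-to-all ratio was low, for example 0.0761 in fibroblasts. Goblet cell marker UMIs were found in 94.7%, 96.0%, 84.8% and 61.3% of the T cells of control 1, control 2, DSS 1 and DSS 2, at median depths of 2578, 2220, 3220 and 2403 UMIs. In fibroblasts the shares were 96.2%, 96.1%, 87.9% and 59.4%, at median depths of 3598, 4801, 4912 and 3806 UMIs. Spink4 (ENSMUSG00000028415) lies on chromosome 4 from 40920052 to 40931395.

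**Figure D4:**
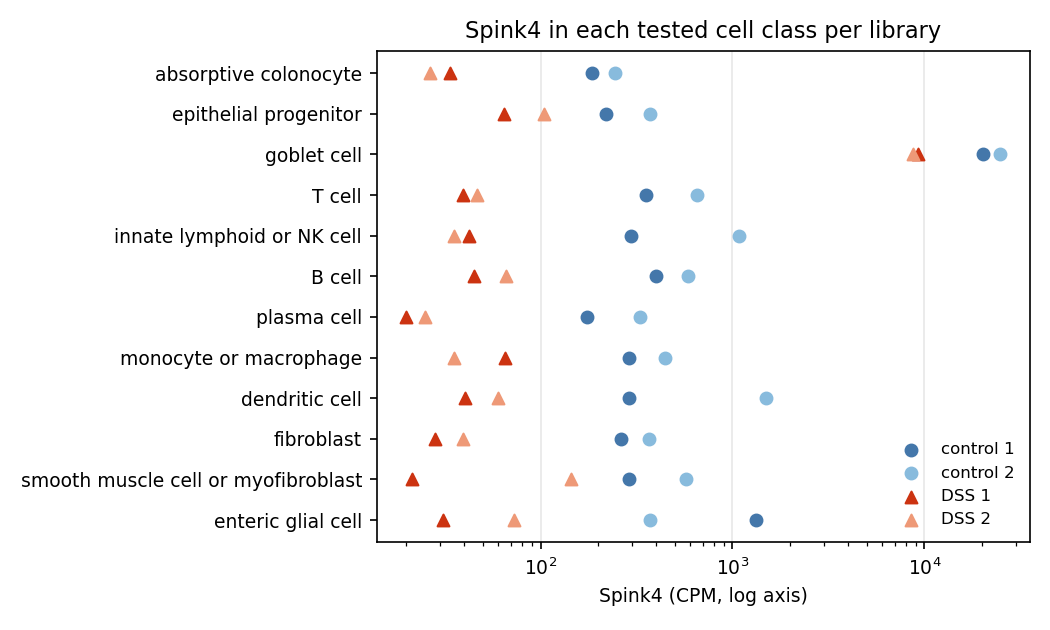
Level of Spink4 (CPM, log axis) in 12 cell classes, with 1 point per library for 2 control and 2 DSS libraries. In colonocytes it lay at 216 CPM ± 42.1 in control and 30.1 CPM ± 4.95 in DSS (SD, n = 2).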

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

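Chosen only after results were seen were the tests of goblet cell markers gene by gene and by the span of their medians, that of interferon-gamma members by their level over all cells, those of the stem cell and interferon-gamma lists within resolution 2 clusters, and the restriction of differences between classes to lists that moved in opposite directions.

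Goblet cell transcripts such as Spink4 were lower after DSS in classes that should lack them. By their first bounds, neither free RNA from epithelial cells (the median log2 fold change of goblet markers spanned 3.03 between 9 classes) nor doublets with goblet cells (172% of the mean of these medians kept with the 5% richest cells removed, a bound set before the result was seen) would account for it. Both bounds were wrong, since they assumed that goblet markers fell together, while over all cells Zg16 and Tff3 lay at 1.78 and 1.75 and Spink4, Muc2 and Agr2 at -2.26, -1.43 and -1.46, so that a median over 6 to 11 markers depends on which markers a class holds. Gene by gene, doublets were argued against, as 97.1% of the markers and classes below -0.5 kept over 50% of their fall without the richest cells. Free RNA remains a candidate explanation, since in 9 of 9 classes the markers' changes correlated with those over all cells (r from 0.898 to 0.962), and it leaves open whether goblet cells were fewer or held less of these transcripts.

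Stem cell and Wnt target genes were lower after DSS in epithelial progenitors, with Lgr5, Ascl2 and Axin2 close to absent. The median was -2.01 with equal cell numbers. This cannot decide whether fewer cells in the DSS libraries mattered, since a random draw of cells leaves the expected levels unchanged. Crypt-base cells placed in other epithelial classes were argued against by a median of -1.73 over all epithelial cells. Another mix of clusters cannot be told apart by the -2.12 in cluster 3 alone, a bound that was wrong because cluster 3 itself mixes the resolution 2 clusters 8 (1152, 388, 16 and 38 cells in control 1, control 2, DSS 1 and DSS 2) and 9 (439, 66, 85 and 437, unnamed at that resolution). Another mix at resolution 2 is a candidate explanation for most of the fall, since in cluster 9 the median was -0.27, while cluster 8 had too few DSS 1 cells to be tested and Axin2 was lower in cluster 9 too (97, 20, 1 and 4 UMIs). Whether such a mix came from DSS removing the crypt-base cells, from a loss of their transcripts that moved them to another cluster, or from dissociation was not tested and stays open.

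Interferon-gamma and antigen presentation genes were higher after DSS in epithelial, stromal and glial classes. Free RNA from immune cells cannot be told apart for the list as a whole, because the list's median lay over 0.5 above that of immune cell markers in 2 of 6 classes (0.51 in colonocytes and 0.87 in glia, against 0.49, -0.54, 0.11 and 0.39 in progenitors, goblet cells, fibroblasts and smooth muscle cells). For the members at over 0.5 of their level over all cells, the median was over 0.5 in 5 of 6 classes. It was 1.56, 1.32, 1.25, 1.24 and 0.77 in progenitors, goblet cells, fibroblasts, smooth muscle cells and glia, and 0.49 in colonocytes. This cannot decide on free RNA, because that level was taken in the group where a member was higher. A rise after DSS thus itself helped a member to enter. Another mix of clusters was argued against by 10 of 11 clusters with a median over 50% of the class value, with fibroblast cluster 18 at 0.48 as the exception, and by 14 of 15 resolution 2 clusters, goblet cells included, with fibroblast cluster 23 at 0.47 as the exception (glia formed 1 cluster and had no test). A response of these cells to interferon is a hypothesis that was not tested. The handling of the libraries was not tested as a cause either.

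Differences between the responses of the 3 large epithelial classes were tested as interaction terms, and 41 of 57 pairs of list and class difference passed with camera at the preset correlation, 4 of them with opposite directions in the 2 classes. With an estimated correlation 0 passed, with 5 at an unadjusted p under 0.05. The transport list differed by 1.13 between progenitors and colonocytes (adjusted p = 9.46e-11) and by 1.51 between goblet cells and colonocytes (adjusted p = 1.43e-09, and 0.474 for both with an estimated correlation). The cytosolic ribosomal protein list differed by -0.998 and -0.959 in the same 2 comparisons (adjusted p = 6.19e-27 and 1.99e-20, and 0.575 for both with an estimated correlation). Ribosomal protein genes were higher in 56 of 56 members in colonocytes (median 0.50, camera adjusted p = 4.72e-08, and 0.73 with an estimated correlation) and lower in 56 of 56 in progenitors (-0.45, 1.37e-05, and 0.777) and in goblet cells (-0.36, 0.000541, and 0.809). In colonocytes the call was lost without control 2 (0.02, adjusted p = 0.856), and the median was 1.27 without control 1. In progenitors it was lost without control 1 (-0.02, adjusted p = 0.922) and was -0.82 without control 2, and in goblet cells it was lost without control 1 (-0.00, adjusted p = 0.9) and was -0.62 without control 2. The response differed in 1688 of 15440 genes between progenitors and colonocytes, in 1405 of 15403 between goblet cells and colonocytes and in 50 of 14301 between goblet cells and progenitors (edgeR interaction term). These differences were not tested with a library left out or within single clusters. In colonocytes the ribosomal protein median was -0.05, 0.04 and 0.25 in the resolution 2 clusters 0, 5 and 7, against -0.32 in progenitors of cluster 9 and -0.25 and -0.38 in goblet cells of clusters 12 and 18. The transport median was -0.08, -0.18 and -0.34, against 0.20 and against 0.56 and 0.95.

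A total of 2 small clusters lay above their level in control. The unnamed cluster 36, in which 77.7% of cells were predicted doublets, made up a mean of 0.091% of DSS cells and 0.0215% of control cells (3, 1, 12 and 9 kept cells in control 1, control 2, DSS 1 and DSS 2). At resolution 2 a neutrophil-like cluster led by S100a9, S100a8 and Retnlg made up 0.074% and 0.0093% (0, 2, 7 and 11 cells). Of its kept cells, 0, 1, 7 and 11 belonged to the monocyte or macrophage class and entered the tests of that class.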

How the results depend on the processing

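Equal cell numbers, cluster 3 alone and the resolution 2 clusters alone were chosen only after results were seen. With all 4 libraries, 274 genes changed over the 12 classes, all in progenitors, and 233 with RLE size factors, 266 with at most 10% mitochondrial UMIs, 273 with at least 1000 UMIs per cell, 252 with doublets kept, 210 at Leiden resolution 0.5 and 244 with the free RNA filter lay within 1.5 times that count. The total was 3601 without the low-count filter, 4098 with the replicate block, 1274 with DESeq2, 91 with equal cell numbers and 0 at Leiden resolution 2 (edgeR, with 6050 at an unadjusted p under 0.05), where progenitors were not tested because DSS 1 held 29 of them. Leaving out each library in turn gave 690 to 1343 genes. Without the low-count filter the counts were 597 in colonocytes, 987 in progenitors, 1191 in goblet cells, 27 in T cells, 22 in innate lymphoid or NK cells, 38 in B cells, 189 in plasma cells, 147 in macrophages, 67 in dendritic cells, 204 in fibroblasts, 94 in smooth muscle cells and 38 in glia. In the same order the replicate block gave 1016, 1183, 916, 75, 33, 69, 104, 86, 117, 392, 99 and 8, and DESeq2 gave 268, 468, 425, 5, 4, 7, 29, 13, 4, 38, 5 and 8. Leave-one-out ranges were 10 to 562, 247 to 714, 0 to 113, 3 to 88, 3 to 8, 0 to 70, 0 to 142, 0 to 63, 0 to 8, 0 to 13, 0 to 53 and 3 to 26. Further counts that moved were 1 in B cells with RLE size factors and 2 in innate lymphoid or NK cells with doublets kept. With equal cell numbers progenitors had 65, innate lymphoid or NK cells 1, B cells 24 and plasma cells 1, and cluster 3 alone had 415 against 274 in progenitors. In single resolution 2 clusters with at least 30 cells of the class in each library, progenitors had 0 in cluster 9 (edgeR, 467 at an unadjusted p under 0.05). Colonocytes had 63, 92 and 162 in clusters 0, 5 and 7, goblet cells 7 in cluster 12, innate lymphoid or NK cells 1 in cluster 25, plasma cells 1 and 2 in clusters 1 and 26, fibroblasts 1, 1 and 4 in clusters 4, 20 and 23, and smooth muscle cells 1 in cluster 29. Equal cell numbers use fewer UMIs, and leaving out a library leaves 3 in the fit. For the other changes the cause was not tested. The replicate numbers are not stated to be a pairing. Between groups, the differences of replicate 1 minus replicate 2 correlated at 0.14 to 0.53 over the 12 classes, all positive, which is a hint from the data and not the design. In progenitors of the resolution 2 cluster 9 alone, 39 of 40 named genes tested kept their direction, Ephb3 turned (0.90) and edgeR passed 0 genes. Of the 42 named genes that passed in the class, 0 turned direction in the alternatives listed next. The number that no longer passed was 0 without the low-count filter, with the replicate block, with at least 1000 UMIs and without control 2. It was 2 with RLE size factors, doublets kept, at most 10% mitochondrial UMIs and DESeq2, 3 at Leiden resolution 0.5 and without DSS 1, 4 without control 1, 12 without DSS 2 and 18 with equal cell numbers.

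At the preset correlation 97 of 180 pairs of gene list and class were called, against 0 with an estimated correlation (smallest adjusted p = 0.55, with 7 at an unadjusted p under 0.05) and 0 with fry (smallest adjusted p = 0.461, with 13 at an unadjusted p under 0.05). The simulated lists show that the estimated correlation called 0 of 12 planted lists at this size. Their genes were drawn independently, so they do not tell which setting is right for lists whose members move together. Other settings gave 87 to 103 calls, and the lowest count with 1 library left out was 70, without DSS 2. Of the 97 calls, 35 held without each library in turn. Lost with the same direction were 0 with RLE size factors, 8 without the low-count filter, 5 with the replicate block, 8 with at most 10% mitochondrial UMIs, 1 with at least 1000 UMIs, 4 with doublets kept, 4 and 9 at Leiden resolutions 0.5 and 2 and 12 with equal cell numbers. Without control 1, control 2, DSS 1 and DSS 2 they were 33, 16, 15 and 36. The direction turned in 7, 3, 1 and 4 calls without these libraries. Cholesterol synthesis genes turned without DSS 2 in colonocytes (leave-one-out median -0.11 to 0.97), goblet cells (-0.0896 to 0.738), fibroblasts (-0.15 to 0.68) and glia (-0.0768 to 0.898). Oxidative phosphorylation genes turned without control 1 in fibroblasts (-0.57 to 0.10) and smooth muscle cells (-0.55 to 0.23), and without control 2 in goblet cells (0.0558 to 0.491, where the direction that camera gives turned although the median stayed positive). Without control 1, B cell activation genes turned in that way in innate lymphoid or NK cells (0.19 to 1.03). Immediate early genes turned without control 1 in dendritic cells (-0.42 to 0.10) and smooth muscle cells (-0.24 to 1.22), and so did ribosomal protein genes in glia (-0.70 to 0.26) and NF-kB genes in smooth muscle cells (-0.0629 to 1.91). Without control 2, ribosomal protein genes (-0.18 to 0.93) and mitochondrially encoded genes (-0.83 to 0.21) turned in dendritic cells. Niche genes turned in smooth muscle cells without DSS 1 (-0.34 to 0.62). With equal cell numbers B cell activation genes in plasma cells turned in camera direction (median 0.18). Of 87 calls with a resolution 2 cluster to test in, 41 had over 50% of the class median in each such cluster. At Leiden resolution 0.5 endoplasmic reticulum stress genes (-0.18) and hypoxia genes (-0.12) turned in innate lymphoid or NK cells. Here too the cause was not tested.

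Shares of cell classes passed in 0 of 18 classes with all 4 libraries and in 0 classes under each alternative run (edgeR). The smallest adjusted p was 0.0991 to 0.996 in leave-one-out, 0.55 with the replicate block, 0.143 and 0.114 at Leiden resolutions 0.5 and 2, 0.735 with at most 10% mitochondrial UMIs, 0.534 with at least 1000 UMIs, 0.697 with doublets kept, 0.743 with TMM on cell numbers and 0.989 within compartments. In simulated data 6 of 67 genes changed 4-fold were recovered in glia, against 40 of 67 in B cells and 20 of 67 in fibroblasts.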

Other observations

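The tests in this part were fixed before the data were examined, except those within resolution 2 clusters, and the gene lists described in it were chosen after their values had been seen.

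In progenitors hypoxia and glycolysis genes were higher as a group in 21 of 28 members (median 0.30, camera adjusted p = 0.00858, and adjusted p = 0.59 with an estimated correlation). Over all genes 2 rose, and 2 rose and 1 fell adjusted over the list alone. Hk1 (log2 fold change 1.22, adjusted p = 0.0272) and Pfkp (1.05, adjusted p = 0.0425), which encode enzymes of early glycolysis, rose, and the vessel growth factor gene Vegfa lay at -1.07 (adjusted p = 0.0671). The call of the list was lost without control 1 (0.39, adjusted p = 0.0613) and without DSS 2 (0.24, 0.193). Hk1 did not pass without DSS 2 (adjusted p = 0.179), nor Pfkp without DSS 1 (0.11) or DSS 2 (0.195). In the resolution 2 cluster 9 alone the list's median was 0.06, and Hk1 and Pfkp lay at 0.39 and 0.22 (adjusted p = 1 for both). In goblet cells p53 target and cell death genes were higher in 23 of 28 members (median 0.36, camera adjusted p = 0.000266, and adjusted p = 0.59 with an estimated correlation), 3 of them passing adjusted over the list alone. Members with small p were the gasdermin genes Gsdmc4 (1.71, adjusted p = 0.126) and Gsdmd (1.07, 0.143), whose products can open pores in membranes. This call was lost without DSS 2 (0.24, adjusted p = 0.107), and the median was 0.22 without control 1, 0.82 without control 2 and 0.66 without DSS 1. NF-kB and inflammatory cytokine genes were higher in goblet cells in 28 of 30 members (median 0.88, camera adjusted p = 2.63e-06, and adjusted p = 0.597 with an estimated correlation). Their median was 0.45 without control 1, 1.48 without control 2 and 0.42 without DSS 2.

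Type I interferon response genes were higher outside the epithelium too, in 22 of 24 members in smooth muscle cells (median 0.67, camera adjusted p = 1.68e-10) and in 29 of 31 in fibroblasts (0.54, 9.66e-09). In dendritic cells they were higher in 24 of 25 members (0.72, 2.4e-07) and in enteric glia in 15 of 17 (0.63, 4.5e-05). With an estimated correlation the adjusted p was 0.608 in fibroblasts and 0.59 in the 3 others. All 4 calls were lost without DSS 2, with medians of 0.24 in smooth muscle cells (adjusted p = 0.0883), 0.05 in fibroblasts (0.525), 0.18 in dendritic cells (0.142) and 0.25 in glia (0.133). Without control 1 the median was 0.45 in dendritic cells, and without control 2 it was 1.32 in dendritic cells and 1.12 in smooth muscle cells. Without DSS 1 it was 1.46 in smooth muscle cells and 0.91 in fibroblasts.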
